A study of Mus musculus with 12 samples.

How the data were processed

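RNA was sequenced from group 2 innate lymphoid cells (ILC2s), lymphocytes that release type 2 cytokines without a rearranged antigen receptor, sorted from skin-draining lymph nodes. Per the labels, congenic mice that received 950 cGy were given a mixture of marrow from CD45.2 Rag1 knockout donors and CD90.1 wild-type donors, and the cells of each donor were taken from these mixed chimeras 8 or 20 weeks later. Before the cells were taken, IL-33, the cytokine that expands these cells, was given at 30 ng to each cheek and 240 ng into the peritoneum on each of 7 days. The 12 libraries form 4 groups of 3: WT at 8 weeks, knockout-labelled at 8 weeks, WT at 20 weeks and knockout-labelled at 20 weeks. The series description gives another length for the later time than the sample labels, and the 20 weeks of the sample labels were used. The labels do not state that the replicates of a group came from separate animals, so p-values measure the spread between these samples. No harvest or sequencing date is given, so time after transplant and any batch that went with it cannot be told apart. Sex-linked genes were read as a list, while Xist, Tsix and the constant segments Trdc and Ighd were not analysed.

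Each deposited file gives, per the file headers, the expected count (estimated number of reads) and the TPM (transcript abundance scaled to a fixed library sum) of each transcript, made with sailfish 0.6.3 from 20-base k-mers against Ensembl release 76. The submitters' processing notes list bcl2fastq, STAR 2.0.4b, Subread and featureCounts 1.4.5, with no role for sailfish; the columns used here are those the file headers name. Per the labels, the RNA was polyadenylated, while the protocol describes removal of ribosomal RNA and random priming; the strand is not stated. The headers record 8 threads for 6 libraries and 24 threads for the other 6; 1 library of each of WT at 8 weeks, knockout-labelled at 8 weeks and WT at 20 weeks ran with 24 threads, as did all 3 knockout-labelled libraries of 20 weeks. Since thread numbers may mark separate runs, they were added as a covariate, and genotype at 8 weeks and time in WT were also fitted on the 6 libraries of 8 threads, 2 per group. The libraries of 24 threads hold 1 of each of 3 groups, too few for values of their own. A k-mer method cannot count reads that differ from the reference at every k-mer, so donor-strain variants can lower an estimate, and reads shared by paralogs are divided by the model.

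Of 86127 transcripts in each file, 83739 (97.2%) were matched by identifier to GENCODE M21 (GRCm38) and summed to 29542 genes; the other 2388 were left out and held 1.01% to 1.54% of the estimated reads of a library. Summed estimated reads were 11433625 to 32529806 per library. Counts were rounded, filtered with filterByExpr in edgeR 4.0.16, scaled by TMM factors and fitted for 14431 genes with the quasi-likelihood model on 4 group means, which gave a common biological coefficient of variation of 0.377. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 in each of 6 contrasts: genotype at 20 weeks, genotype at 8 weeks, genotype averaged over both times, the genotype by time interaction, and time in each genotype. Each time contrast shares its libraries with the genotype contrasts, so their values are not independent. TMM-scaled CPM (counts scaled to library size) are given as mean ± SD over the 3 libraries of a group, and log2 fold changes carry a standard error (SE). Deposited TPM values entered only as length-scaled counts among the alternatives. Where a gene was at 0 in all libraries of a group, the fold was computed against a floor of 3 counts per library; floors cover counting error only, since PCR copies are not independent molecules. The fitted log2 values of such genes rest on the prior count and are no bound.

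The choices named here were made before the data were examined: the tests, the gene lists and the rule for named genes. Of 32 lists, the 30 with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists within a contrast; the estimated correlation and fry were run beside it. The lists held genes of ILC2 identity, type 2 cytokines and effectors, immediate early genes, costimulation and checkpoint receptors, NF-kB and IL-33 signalling, targets and brakes of IL-2, IL-7 and STAT5, cell cycle, p53 targets, double-strand break repair, interferon-stimulated genes, MHC class I, naive-like genes, migration receptors, neuropeptide and lipid mediator receptors, glycolysis, sterol synthesis, fatty acid use, oxidative phosphorylation, heat shock and unfolded protein response, mitochondrially encoded genes, markers of 9 other cell types, sex-linked genes, and genes near Rag1 and near Thy1. A list's members at 0 in a group were also set to their bound, which moved the median of no called list by more than its rounding. Named genes were fixed as follows: Rag1, Rag2, Thy1, Ptprc, Gata3, Il1rl1, Klrg1, Icos, Il5, Il13, Areg and Csf2 always; in each contrast up to 10 higher and 10 lower called genes with the largest change, a mean log2 CPM of at least 1 and no overlap between the groups' libraries (within each time for the average, not required for the interaction); the 5 smallest p-values where fewer qualified; and up to 4 members of a described list with the smallest p. Gene models without an ordinary symbol were counted and not named. Genes named outside this rule are marked as chosen after their values were seen.

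Positions of called genes were compared with all tested genes by Fisher's exact test, 2-sided, for a window of 10 Mb to each side of Rag1 or Thy1. Summed reads of antigen receptor segments were compared by an exact permutation test, 1-sided, within each time and without regard to replicate number. The fit was tested on simulated data with 200 changed genes among 14431, 100 at each of 2 sizes. Of the 100 with a true log2 change of 1 it recovered 12% at either time and 47% in the average, and of the 100 with a log2 change of 2 it recovered 83% at 20 weeks, 81% at 8 weeks and 95% in the average, with 5, 5 and 7 false calls. A simulated list of 25 shifted genes was called and 0 of 20 unchanged lists were (camera). The simulated genes varied independently of one another, so this does not show how the test behaves on lists with correlated members. Both times were simulated with the same spread. Recovery and false calls may therefore differ in the real data, where the libraries of 8 weeks correlated less within their groups. Alternatives covered DESeq2 1.42.0 size factors and Wald test, limma-voom, no filter, a filter at 10 reads, length-scaled counts, a fit of only the groups compared, a replicate block, and each library left out in turn. Leaving out both libraries that stood apart at 8 weeks, the fits by thread number and the 10 Mb window with the replicate block were chosen after the data were seen. Whether equal replicate numbers mark cells of the same mouse is not stated. Deviations from the group mean correlated by 0.11 to 0.29 between WT and knockout-labelled libraries of equal number at 8 weeks and by -0.26 to 0.05 between the others. At 20 weeks they correlated by 0.08 to 0.15 and by -0.19 to 0.06. With every pair over 0.1 at 8 weeks, the numbers were read as pairs there. At 20 weeks the equal-number pairs also lay above all others, though not all over 0.1. Values with the replicate number as a block are given beside the genotype counts. Analyses ran in R 4.3.3 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.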

Results

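Transcript abundance was measured by RNA sequencing in IL-33-expanded ILC2s from 4 groups of 3 libraries, WT and knockout-labelled cells at 8 and at 20 weeks after transplant. Estimated reads per library were 29143897, 24295275 and 13214097 for WT at 20 weeks and 32529806, 32254495 and 21510559 for knockout-labelled cells at 20 weeks. They were 24011859, 11433625 and 17121558 for WT at 8 weeks and 28618535, 21249315 and 16397951 for knockout-labelled cells at 8 weeks. Among the 20-week libraries the mean correlation of a library with its group was 0.949 to 0.975, and among the 8-week libraries 0.879 to 0.939. Of the 8-week libraries, 2 stood apart in a principal component analysis: WT replicate 2 on the first component (31.6% of variance) and knockout-labelled replicate 3 on the second (19.5%). In the latter the 10 most abundant genes took 24.53% of reads, against 8.85% to 15.03% in the other 11 libraries.

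The first question was whether the libraries carried the marks of their donors. Rag1 (ENSMUSG00000061311, chromosome 2, 101638282 to 101649501, GRCm38), which encodes a subunit of the V(D)J recombinase, had 0 estimated reads in all 6 WT libraries. In the knockout-labelled libraries it had 13.2, 18.4 and 10.8 estimated reads at 20 weeks and 0, 14.5 and 12.2 at 8 weeks. Rag1 was therefore at least 3.19-fold higher in knockout-labelled cells at 20 weeks (0.457 ± 0.0773 CPM, n = 3) and at least 2.78-fold higher at 8 weeks (0.567 ± 0.508 CPM, n = 3), against floors of 0.143 and 0.204 CPM in WT. This direction goes against the labels, and the difference averaged over times did not pass the test (adjusted p = 0.377). The labels do not give the part of Rag1 removed from the knockout allele, and the estimates span whole transcripts, so the reads cannot be placed inside or outside that part. Nor do they tell whether the genotype labels are exchanged, which would turn the sign of every genotype fold change, and the labels were used as given. Rag2 (ENSMUSG00000032864, chromosome 2, 101624718 to 101632529), which encodes the partner subunit, lay between 1.16 and 6.13 CPM in all 12 libraries. It was not called between genotypes (log2 fold change averaged over times -0.28, SE 0.31, adjusted p = 1).

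Thy1 (ENSMUSG00000032011, chromosome 9, 44043384 to 44048579), which encodes CD90, the surface protein whose allele marked the WT donors, separated the genotypes in every library. It lay between 2.96 and 5.7 CPM in the 6 WT libraries and between 16.8 and 37.8 CPM in the 6 knockout-labelled libraries. Its log2 fold change averaged over times was 2.63 (SE 0.25, adjusted p = 0.000463). Ptprc, which encodes CD45, whose alleles tell recipients from knockout donors, had a log2 fold change of -0.12 (SE 0.19, adjusted p = 1). Thy1 differed the same way at both times, which does not show which genotype carries which label. Summed reads of immunoglobulin V segments, whose joining needs Rag1, were at 52.2, 161 and 3.02 CPM in knockout-labelled libraries of 8 weeks. In WT libraries of that time they were at 3.23, 7.41 and 6.31 CPM. At 20 weeks they were lower in knockout-labelled cells (4.41 ± 1.87 against 53.6 ± 17.3 CPM). T cell receptor constant segments were lower in knockout-labelled cells at both times. The sums do not test the labels, since the mice also received WT marrow and segments never joined count as well.

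The design asks how ILC2s that developed with and without Rag1 differ, and genotype averaged over both times uses all 12 libraries for it. The Notch ligand gene Jag1 (ENSMUSG00000027276, chromosome 2, 137081456 to 137116644) fell from 33.4 ± 20.7 to 3.21 ± 0.816 CPM at 8 weeks and from 11.5 ± 3.93 to 1.44 ± 0.293 CPM at 20 weeks (n = 3 each). Its averaged log2 fold change was -3.19 (SE 0.32, adjusted p = 0.000794). The gene for the transcription factor Ets1 (ENSMUSG00000032035, chromosome 9, 32636221 to 32757820) was higher in knockout-labelled cells (averaged log2 fold change 2.48, SE 0.32, adjusted p = 0.004). It was at 3060 ± 2460 against 182 ± 3.61 CPM at 8 weeks and at 1870 ± 417 against 1010 ± 112 CPM at 20 weeks. Itgae (ENSMUSG00000005947, chromosome 11, 73090583 to 73147446), which encodes the integrin chain CD103, was lower (-1.22, SE 0.19, adjusted p = 0.0158). It was at 33.8 ± 10.4 against 102 ± 21.7 CPM at 8 weeks and at 68.5 ± 15.4 against 123 ± 23.3 CPM at 20 weeks. Tmprss13, a transmembrane serine protease gene, was at 0.0728 ± 0.126 CPM in WT cells of 8 weeks and 0.295 ± 0.289 CPM at 20 weeks. It reached 28.7 ± 29.1 and 9.91 ± 2.87 CPM in knockout-labelled cells (6.70, SE 0.78, adjusted p = 0.00213).

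Of 14431 genes tested, 32 were called in this average, 15 higher and 17 lower in knockout-labelled cells. Of these, 28 had a log2 change of at least 1 in size, and 4 lay on the Y chromosome. The Y genes Ddx3y, Eif2s3y and Uty were high only in the WT libraries of 20 weeks, so a call in the average can come from 1 time. Besides Tmprss13, Thy1 and Ets1, the higher genes included Nxpe4 (log2 fold change 1.61), Me3, a malic enzyme gene (1.41), Vwa5a (0.94) and Asb18 (0.85). The lower genes included Dapk2, a death-associated kinase gene (-2.54), Fam219b (-1.93), Ubash3b, a phosphatase that dampens antigen receptor signalling (-1.84), and Cat, which encodes catalase (-0.58). Catalase transcripts were at 112 ± 4.72 against 175 ± 12.5 CPM at 8 weeks and 121 ± 7.68 against 173 ± 8.3 CPM at 20 weeks (SE 0.10, adjusted p = 0.0407). This was the smallest change among the named called genes. The call of Cat was lost in 15 of its 21 alternatives, that of Vwa5a in 11, Asb18 in 9 and Itgae in 4. Thy1, Jag1, Ets1, Nxpe4, Me3 and Dapk2 stayed past the threshold in all 21. With the replicate number as a block, 19 genes were called, and the calls of Cat, Vwa5a, Asb18, Fam219b and Ubash3b were lost. With the thread number as a covariate 28 were called.

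**Figure D1:**
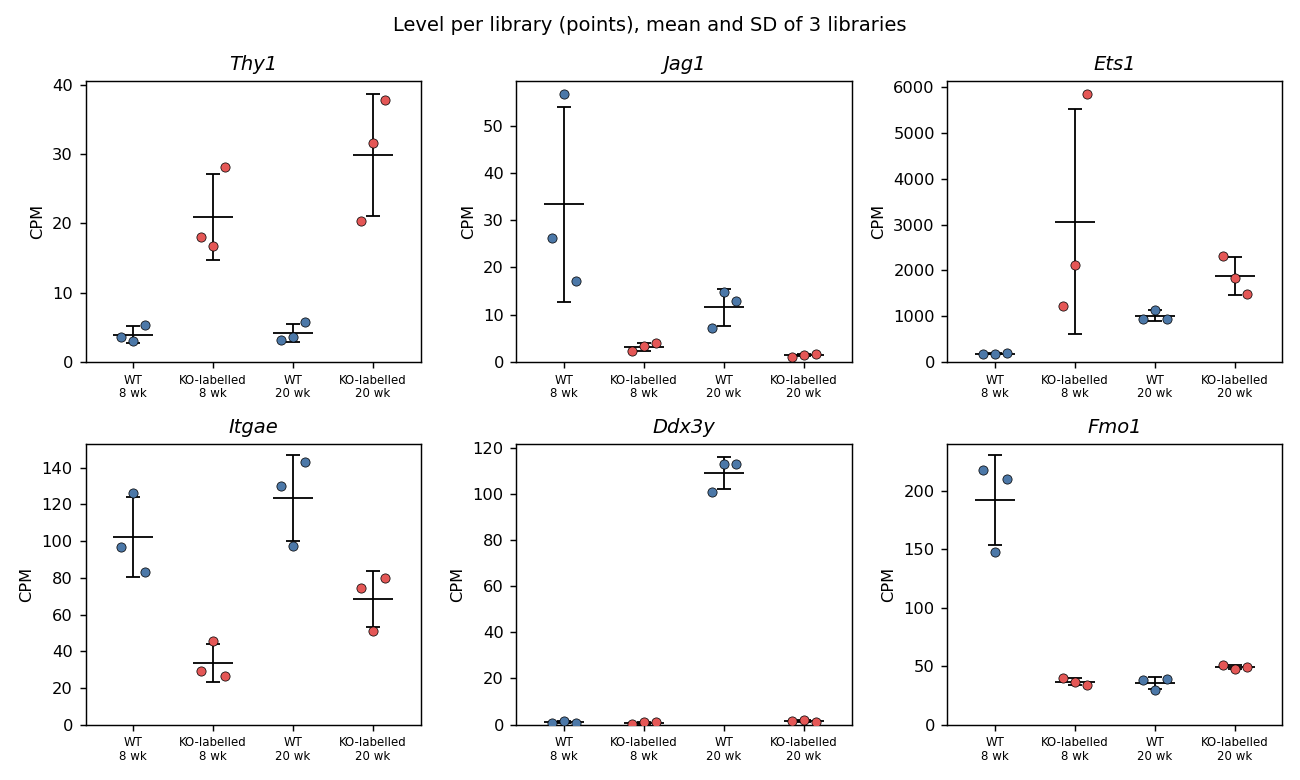
CPM of 6 genes in each of the 12 libraries (points), by genotype and time, with the group mean and SD (bars). Thy1 lay at 16.8 to 37.8 CPM in knockout-labelled libraries and at 2.96 to 5.7 CPM in WT libraries, Ddx3y was high only in the WT libraries of 20 weeks (109 ± 7.01 CPM), and Fmo1 only in the WT libraries of 8 weeks (192 ± 38 CPM).

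Of 8 ILC2 genes fixed beforehand, 0 were called between genotypes in the average by edgeR, DESeq2 or limma-voom, with 0 at an unadjusted p under 0.05. In this average, log2 fold changes were 0.24 (SE 0.21) for Gata3, the lineage's transcription factor, 0.01 (SE 0.15) for Il1rl1, the IL-33 receptor, 0.09 (SE 0.15) for Klrg1 and -0.03 (SE 0.20) for Icos, each with an adjusted p of 1. The type 2 cytokine gene Il5 was at 163 ± 40.3 against 161 ± 18.9 CPM at 8 weeks and 158 ± 16.4 against 146 ± 9.09 CPM at 20 weeks (0.07, SE 0.14). Il13 (0.18, SE 0.23), Areg (0.26, SE 0.27) and Csf2 (-0.27, SE 0.26) also had an adjusted p of 1. Of 23 tested genes of the ILC2 identity list, 1 was higher over all genes in edgeR, Ets1, while DESeq2 called 1 higher and 1 lower. Adjusted over the list alone, 1 was higher and 1 lower (median log2 fold change -0.02, camera adjusted p = 0.8). Il18r1, the IL-18 receptor chain on the same list, had a log2 fold change of -0.80 (SE 0.17, adjusted p = 0.134) and was the lower gene in DESeq2. Of 18 type 2 cytokines and effectors, 0 were called in edgeR or limma-voom, 1 was lower in DESeq2 and 3 at an unadjusted p under 0.05. Adjusted over the list alone 1 was lower (median 0.07, camera adjusted p = 0.55). Of 22 migration and residency receptors, 1 fell over all genes and adjusted over the list alone, Itgae (median -0.02, camera adjusted p = 0.404). At an SE of 0.25 for the median gene, a log2 change of 1 was recovered in 47% of simulated genes, so smaller differences could not be excluded at this replication.

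**Figure D2:**
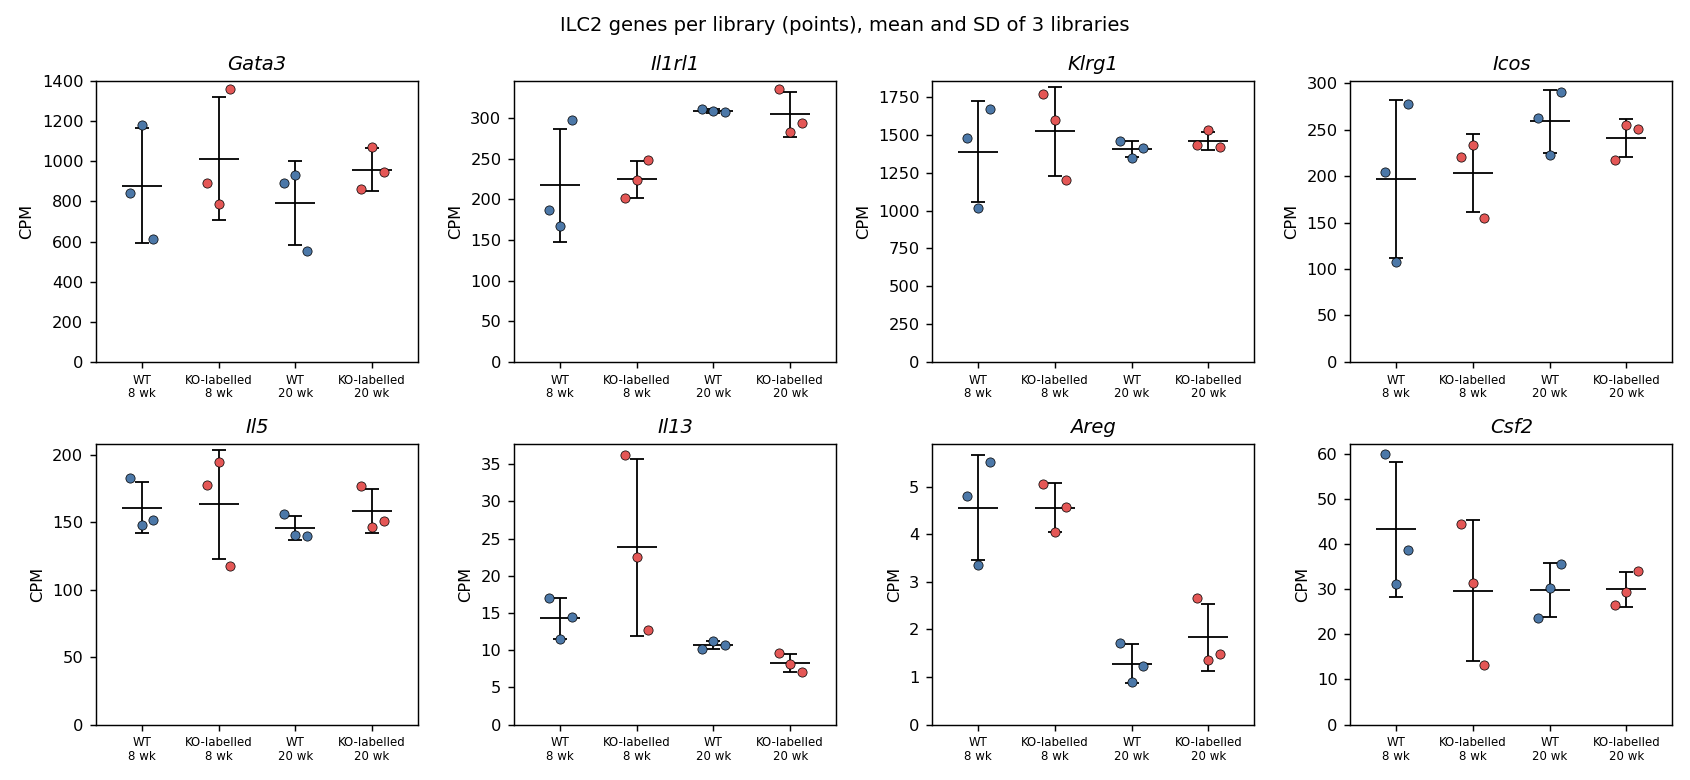
CPM of Gata3, Il1rl1, Klrg1, Icos, Il5, Il13, Areg and Csf2 in each of the 12 libraries (points), by genotype and time, with the group mean and SD (bars). No genotype comparison of these genes passed the test, and Il5 group means ran from 146 to 163 CPM.

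T cell markers were lower as a list in knockout-labelled cells. Over 17 tested members the median averaged log2 fold change was -0.29 (camera adjusted p = 0.00239; adjusted p = 0.0839 with an estimated correlation). Of these members 0 were called over all genes in edgeR or limma-voom and 1 in DESeq2. Of the list, 2 were lower adjusted over its members alone, and 5 at an unadjusted p under 0.05. The 4 members with the smallest p were the CD3 chain gene Cd3e (-3.14, SE 0.88), the kinase gene Lck (-0.61, SE 0.18), and the receptor chain genes Cd3g (-0.50, SE 0.18) and Cd247 (-0.54, SE 0.20). Cd3e (chromosome 9, 44998740 to 45009627) and Cd3g (44969572 to 44980431) lie close to Thy1. At 20 weeks the list's median was -0.32 and its mean -0.09 (camera adjusted p = 0.0313; adjusted p = 0.388 with an estimated correlation). At 8 weeks the median was -0.21 (camera adjusted p = 0.0281; adjusted p = 0.303 with an estimated correlation). At either time 0 members were called over all genes in edgeR, limma-voom or DESeq2 or adjusted over the list alone, with 1 and 2 lower at an unadjusted p under 0.05. The call at 20 weeks was lost without WT replicates 1 (adjusted p = 0.124) or 3 (0.0804) or knockout-labelled replicates 2 (0.179) or 3 (0.0745) of that time, and without knockout-labelled replicate 2 of 8 weeks (0.0592). The call at 8 weeks was lost without WT replicates 1 (0.0657) and 3 (0.0785) or knockout-labelled replicates 1 (0.0819) and 3 (0.0885) of 8 weeks, and among the libraries of 8 threads (0.0586).

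At 20 weeks alone, the clearest genotype differences were on the Y chromosome. Ddx3y, an RNA helicase gene, was at 1.48 ± 0.402 CPM in knockout-labelled cells and 109 ± 7.01 CPM in WT cells (n = 3 each; log2 fold change -6.18, SE 0.41, adjusted p = 2.1e-05). Eif2s3y, which encodes a translation initiation factor subunit, was at 1.58 ± 0.446 against 140 ± 21 CPM (-6.46, SE 0.52, adjusted p = 0.000118), and Uty, of the histone demethylase family, at 2.26 ± 0.32 against 49.9 ± 2.59 CPM (-4.46, SE 0.28, adjusted p = 1.91e-05). Off the Y chromosome, Thy1 was higher in knockout-labelled cells (2.86, SE 0.35, adjusted p = 0.00974) and Jag1 lower (-3.00, SE 0.45, adjusted p = 0.0413). The calpain gene Capn11 (ENSMUSG00000058626, chromosome 17, 45630204 to 45659325) was at 4.47 ± 1.67 against 0.282 ± 0.244 CPM (3.79, SE 0.56, adjusted p = 0.0361). In all, 8 genes were called at 20 weeks, 3 higher and 5 lower, 4 of the lower ones on the Y chromosome. Of Y genes tested, Kdm5d, chosen after its values were seen, was at 51.5 ± 2.47 CPM in WT cells and 26.6 ± 2.11 CPM in knockout-labelled cells (-0.96, SE 0.23, adjusted p = 0.64). The count fell to 3 without WT replicate 1 or 2 or knockout-labelled replicate 2 or 3 of 20 weeks, to 4 without knockout-labelled replicate 1 of 20 weeks and to 5 without WT replicate 1 of 8 weeks. It was 15 without knockout-labelled replicate 3 of 8 weeks and 20 without both libraries that stood apart at 8 weeks. With the thread number as a covariate it was 3. Fitted on the 6 libraries of 20 weeks alone it was 17 (limma-voom 25, DESeq2 85), with 771 genes at an unadjusted p under 0.05. Ddx3y, Eif2s3y and Uty were called in all 22 alternatives, while the call of Capn11 was lost in 13, that of Jag1 in 12 and that of Thy1 in 5. With the replicate number as a block 4 genes were called, and Capn11 (adjusted p = 0.235) and Jag1 (adjusted p = 0.2) were lost.

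Of the gene lists, B cell markers were lower in knockout-labelled cells at 20 weeks, with a median log2 fold change of -0.70 over 14 tested members (camera adjusted p = 0.000476; adjusted p = 0.629 with an estimated correlation). Of these members 0 were called over all genes in edgeR, limma-voom or DESeq2. Adjusted over the list alone 2 were lower, and 3 at an unadjusted p under 0.05. Igkc, the kappa light chain constant segment, was at 6.42, 2.67 and 2.76 CPM in knockout-labelled libraries and at 51.9, 32.6 and 43.5 CPM in WT libraries. Jchain, the joining chain of secreted antibodies, had a log2 fold change of -3.32 (SE 1.01, adjusted p = 1). Type 2 cytokines and effectors were lower as a list (median -0.19, camera adjusted p = 0.0153; adjusted p = 0.629 with an estimated correlation), with 0 members called over all genes in edgeR or limma-voom and 1 in DESeq2. Of the list, 1 was lower adjusted over its members alone, and 2 at an unadjusted p under 0.05. Of them, the chemokine gene Ccl22 was at 0 in all 3 knockout-labelled libraries and at 0.617 ± 0.215 CPM in WT. Tnfsf8, which encodes CD30 ligand, had a log2 fold change of -0.88 (SE 0.34, adjusted p = 1). This list's call was lost without WT replicate 1 (adjusted p = 0.093) or knockout-labelled replicate 2 (0.179) of 20 weeks.

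At 8 weeks many of the called genes were set apart by the WT libraries of that time, including Fmo1, Adamts13, Pes1 and Nefh. Fmo1, a flavin monooxygenase gene, was at 36.8 ± 3.21 CPM in knockout-labelled cells and 192 ± 38 CPM in WT cells (log2 fold change -2.38, SE 0.19, adjusted p = 0.000225). Adamts13, which encodes the protease that cleaves von Willebrand factor, was at 1.91 ± 0.251 against 15.9 ± 3.3 CPM (-3.05, SE 0.30, adjusted p = 0.000609). Pes1, a ribosome biogenesis gene, was higher, 170 ± 25.4 against 39.2 ± 8.31 CPM (2.11, SE 0.22, adjusted p = 0.00108). The neurofilament gene Nefh was at 0 in all 3 WT libraries and at 16.4 ± 4.39 CPM in knockout-labelled cells, at least 80.3-fold higher. Gal3st1, a cerebroside sulfotransferase gene, was at least 15.3-fold higher (3.11 ± 1.71 CPM against 0).

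In total 29 genes were called at 8 weeks, 15 higher and 14 lower in knockout-labelled cells. Higher genes included Tmprss13 (log2 fold change 8.13), Ets1 (4.07), Coro2b, an actin-binding coronin gene (3.72), and Thy1 (2.40). Also higher were Eri3 (2.15), Mid1, a ubiquitin ligase gene (1.85), and Nxpe4 (1.71). Lower genes included Jag1 (-3.39), Capn11 (-3.13), the keratin gene Krt80 (-2.70) and Cdk5rap1, a modifier of mitochondrial transfer RNA (-2.48). Also lower were Fam219b (-2.43), Cpne8 (-2.16), Sgip1 (-2.15) and Itgae (-1.59). Ets1 was at 178, 181 and 185 CPM in the WT libraries of 8 weeks and at 1210, 2120 and 5850 CPM in the knockout-labelled ones. The count was 15 without WT replicate 1 and 16 without knockout-labelled replicate 1 of 8 weeks. With the thread number as a covariate it was 29. Fitted on the 6 libraries of 8 weeks alone it was 8 (limma-voom 4, DESeq2 41), with 225 genes at an unadjusted p under 0.05. In such separate fits 20 weeks, with 17, had more called genes than 8 weeks. Among the 6 libraries of 8 threads, 2 per group, edgeR and limma-voom called 0 and DESeq2 50, with 467 at an unadjusted p under 0.05. These 467 held all 29 genes, each in the same direction, but these libraries helped to choose the genes, so this is no separate support. With the replicate number as a block 15 genes were called, and Gal3st1, Tmprss13, Coro2b, Eri3, Mid1, Nxpe4, Jag1, Capn11, Fam219b and Sgip1 were lost. Adamts13, Fmo1 and Nefh were called in 22 of 23 alternatives and lost only among the libraries of 8 threads, while Eri3 was lost in 12, Mid1 in 14 and Itgae in 11.

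B cell markers were higher as a list in knockout-labelled cells at 8 weeks, the direction opposite to that at 20 weeks. The median log2 fold change was 1.71 over 14 members (camera adjusted p = 1.3e-05; adjusted p = 0.441 with an estimated correlation), with 0 members called over all genes in edgeR or limma-voom and 1 higher in DESeq2. There were 3 higher adjusted over the list alone, and 5 at an unadjusted p under 0.05. Igkc was at 57.3, 170 and 2.2 CPM in the 3 knockout-labelled libraries and at 8.69, 13.8 and 7.11 CPM in WT. Cd79a, a chain of the B cell receptor, reached 24.2 CPM in knockout-labelled replicate 2. Without that replicate the list's adjusted p was 0.166, and among the libraries of 8 threads, which exclude it, 0.611. Immediate early genes, which respond within minutes to stimulation, had a median of -0.14 (camera adjusted p = 0.0486; adjusted p = 0.579 with an estimated correlation), with 0 of 25 members called in edgeR, limma-voom or DESeq2 or adjusted over the list alone, and 1 lower at an unadjusted p under 0.05. This call was lost without WT replicate 1 (adjusted p = 0.275), WT replicate 2 (0.0829) or knockout-labelled replicate 3 (0.979) of 8 weeks. It was also lost without WT replicate 1 (0.0529), knockout-labelled replicate 1 (0.0537) or replicate 3 (0.0503) of 20 weeks.

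Few genes were called at both times. Thy1 and Gm7658, a gene model chosen after its values were seen, were higher in knockout-labelled cells at 8 and at 20 weeks, and Jag1 was lower at both, against 0 genes expected by chance in either direction. Capn11 was called in opposite directions. At an unadjusted p under 0.05, 21 genes were higher and 26 lower at both times, with 2.7 expected each way, and 15 went in opposite directions, with 5.4 expected. With the replicate number as a block 1 gene, Thy1, was called the same way at both times. Across the 14431 genes, which are not independent replicates, the log2 fold changes of both times had a Pearson correlation of 0.11 and a Spearman correlation of 0.09.

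Because the donors were built around targeted or congenic loci, the positions of the called genes were compared with Rag1 and Thy1. Within 10 Mb of either locus, 9 of 229 tested genes were called in the average, against 23 of 14202 elsewhere (odds ratio 25.2, 95% interval 10.1 to 57.4, Fisher's exact p = 1.11e-09). Near Thy1 these were 6 of 141 genes (odds ratio 24.4, exact p = 5.75e-07). Among them were Thy1, Tmprss13 (chromosome 9, 45319100 to 45347581), Nxpe4 (48162023 to 48400025) and Vwa5a (38718268 to 38743337), all higher in knockout-labelled cells. Ubash3b (41011098 to 41161697) was lower. Near Rag1 they were 3 of 88 genes (odds ratio 17.4, exact p = 0.000956), with Cat (chromosome 2, 103453849 to 103485160) the only one with an ordinary symbol. At single times, 0 of the 88 genes near Rag1 were called at 20 weeks and 1 at 8 weeks (exact p = 1 and 0.163). Near Thy1, 1 was called at 20 weeks and 3 at 8 weeks (exact p = 0.0756 and 0.00277), but with the replicate number as a block 1 at 8 weeks, Thy1 (odds ratio 7.28, exact p = 0.137). With this block, the average had 3 calls near Thy1 (odds ratio 19.4, exact p = 0.000789), which were Thy1, Tmprss13 and Nxpe4. It then had 1 call near Rag1, not Cat (odds ratio 9.14, exact p = 0.11). Outside the windows, Jag1 (137081456 to 137116644) lies on chromosome 2 with Rag1, and Ets1, Coro2b, Fam219b and Dapk2 lie on chromosome 9. Chromosome 9 as a whole, the 6 calls near Thy1 included, held 10 of the 32 called genes (31.2%). It held 5.5% of the genes tested (odds ratio 7.85, exact p = 5.35e-06). This test was not among those fixed beforehand, and it is not separate from the window near Thy1. On the gene lists fixed for both loci, 3 of 87 members were called (odds ratio 17.6, 95% interval 3.37 to 58.6, exact p = 0.000925), and with the block 1 (odds ratio 9.25, exact p = 0.109). The list near Rag1 alone had 1 call, Cat (exact p = 0.0972). The chromosome 9 list held 1 higher and 1 lower gene over all genes, and 3 higher and 5 lower adjusted over the list alone (median 0.05, camera adjusted p = 0.55). The chromosome 2 list held 1 lower gene over all genes, and 1 higher and 1 lower adjusted over the list alone (median 0.08, camera adjusted p = 0.566). Genes near Thy1 reached an unadjusted p under 0.05 in 20.6% of cases, 15 higher and 14 lower, and genes near Rag1 in 6.8%, against 3.5% elsewhere.

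Whether the genotype difference itself depended on time was tested as an interaction, which called 14 genes, 6 with a more positive and 8 with a more negative genotype difference at 20 weeks. Capn11 was at 37.8 ± 3.47 CPM in WT cells of 8 weeks and 0.282 ± 0.244 CPM in those of 20 weeks. In knockout-labelled cells it was at 4.27 ± 1.62 and 4.47 ± 1.67 CPM (interaction 6.92, SE 0.74, adjusted p = 0.00128). Fmo1 (2.87, SE 0.27, adjusted p = 0.000462), Adamts13 (3.47), Cdk5rap1 (2.63) and Hectd4, a ubiquitin ligase family gene (5.12), followed the same direction. Ddx3y (-5.94), Eif2s3y (-6.19), Uty (-4.59), Nefh, Mid1 (-2.74) and Pes1 (-2.03) went the other way. The interaction of Ets1 was -3.18 (SE 0.62, unadjusted p = 0.000229, adjusted p = 0.144). It was not called in edgeR over all genes, but was called in DESeq2, in 4 of 21 alternatives in all, and adjusted over the ILC2 identity list alone. That of Itgae was 0.74 (SE 0.37, adjusted p = 1), so its call at 8 weeks and not at 20 weeks was not shown to differ between times. The calls of Hectd4 (13 of 21 alternatives), Mid1 (14), Cdk5rap1 (12) and Pes1 (11) were the ones most often lost. With the replicate number as a block 9 genes were called, without these 4 and Adamts13, and with the thread number as a covariate 10.

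Of the lists, B cell markers had a median interaction of -2.66 over 14 members (camera adjusted p = 4.42e-11; adjusted p = 0.219 with an estimated correlation), with 0 members called over all genes in edgeR or limma-voom and 2 lower in DESeq2. Adjusted over the list alone 3 were lower, and 6 at an unadjusted p under 0.05. Type 2 cytokines and effectors had a median of -0.35 (camera adjusted p = 0.0391; adjusted p = 0.604 with an estimated correlation), with 0 members called over all genes in edgeR or limma-voom and 1 lower in DESeq2. Of the list, 1 was lower adjusted over its members alone, and 4 at an unadjusted p under 0.05. Mast cell, basophil and eosinophil markers had a median of 0.68 over 7 members (camera adjusted p = 0.0151; adjusted p = 0.219 with an estimated correlation), with 0 members called in edgeR, limma-voom or DESeq2 or adjusted over the list alone, and 2 higher at an unadjusted p under 0.05. Of these, the carboxypeptidase gene Cpa3 had an interaction of 0.90 (SE 0.36, adjusted p = 1), and Mcpt8 was at 0 in WT cells of 20 weeks and at or under 0.796 CPM in the other groups. The type 2 call was lost without WT replicate 1 (adjusted p = 0.0968) or 3 (0.0696) or knockout-labelled replicate 2 (0.144) of 20 weeks. It was also lost without WT replicate 1 (0.0769) or 2 (0.155) or knockout-labelled replicate 1 (0.195) or 2 (0.238) of 8 weeks. The mast cell call was lost without WT replicate 3 of 20 weeks (0.0696), WT replicate 1 (0.0769) or 3 (0.0846) or knockout-labelled replicate 3 of 8 weeks (0.187).

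The comparison of 20 with 8 weeks asked how ILC2s of 1 genotype differed with time after transplant. In WT cells, genes of the immediate early response fell. Nr4a1, which encodes an orphan nuclear receptor, fell from 190 ± 51.1 to 18.9 ± 6.47 CPM (n = 3 each; log2 fold change -3.33, SE 0.39, adjusted p = 0.00123), and its relative Nr4a2 from 6.7 ± 1.8 to 0.205 ± 0.0908 CPM (-4.96, SE 0.55, adjusted p = 0.00109). Fos, a subunit of the transcription factor AP-1, fell from 1050 ± 159 to 215 ± 14 CPM (-2.29, SE 0.26, adjusted p = 0.00109), and Tnfaip3, which encodes the NF-kB inhibitor A20, from 216 ± 61.9 to 37.4 ± 5.87 CPM (-2.53, SE 0.25, adjusted p = 0.000346). Of 25 tested immediate early genes 9 fell over all genes, and 17 were lower adjusted over the list alone. Further examples were the phosphatase gene Dusp1 (-2.03), Egr1 (-2.15) and the activation marker Cd69 (-1.55), chosen after their values were seen, with the call of Egr1 lost in 13 of 23 alternatives. The list's median was -1.25 (camera adjusted p = 1.32e-31; adjusted p = 0.0084 with an estimated correlation), and it was called in all 18 alternatives.

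In all, 74 genes were called in WT cells, 29 higher and 45 lower at 20 weeks, 8 of them on the Y chromosome. Higher were the Y genes Eif2s3y (log2 fold change 7.42), Ddx3y (6.80) and Uty (4.90), Nefh (at least 54.6-fold) and Gal3st1 (at least 11.2-fold). Coro2b (2.52), Ets1 (2.47), Mid1 (2.42), Emp1 (2.18) and P2rx7, an ATP-gated channel gene (2.13), were also higher, of which the calls of P2rx7, Emp1 and Ets1 were lost in 15, 13 and 11 of 23 alternatives. Lower, besides the genes above, were Capn11 (-6.87), Hectd4 (-4.10), Rgcc (-3.59), Adamts13 (-3.52), Cd163l1 (-3.13), Cpne8 (-2.71), Rasd1 (-2.45) and the cell cycle inhibitor gene Cdkn1a (-2.10). The count depended on single libraries: it was 36, 29 and 35 without WT replicates 1, 2 and 3 of 20 weeks, and 38 and 302 without WT replicates 1 and 3 of 8 weeks. It was 49 without knockout-labelled replicate 2 of 20 weeks and 151 without knockout-labelled replicate 3 of 8 weeks. It was 156 without both libraries that stood apart at 8 weeks and 57 with the thread number as a covariate. Among the 6 libraries of 8 threads, edgeR and limma-voom called 0 and DESeq2 218, with 1147 at an unadjusted p under 0.05. These 1147 held all 74 genes, each in the same direction, but these libraries helped to choose the genes, so this is no separate support.

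Interferon-stimulated genes were also lower at 20 weeks in WT cells, with a median of -1.04 over 30 members (camera adjusted p = 2.1e-15; adjusted p = 0.348 with an estimated correlation). Of them 2 fell over all genes, Mx1 (-2.01) and Oasl1 (-2.43), and 18 were lower adjusted over the list alone. The calls of Mx1 and Oasl1 were lost in 15 and 14 of 23 alternatives, and of the list limma-voom called 0 and DESeq2 13, with 20 lower at an unadjusted p under 0.05. NK cell and ILC1 markers had a median of -1.23 over 10 members (camera adjusted p = 0.000777; adjusted p = 0.0636 with an estimated correlation), with 0 called over all genes in edgeR or limma-voom and 3 lower in DESeq2. Adjusted over the list alone 3 were lower, and 4 at an unadjusted p under 0.05. The chemokine gene Ccl5 was at 1260 ± 687 CPM at 8 weeks and 435 ± 66.9 at 20 weeks, and granzyme gene Gzmb at 50.3 ± 33 and 9.05 ± 8.68. Cell cycle genes (median -0.25, camera adjusted p = 0.000551) and heat shock and unfolded protein response genes (-0.32, 0.00399) were lower as lists (each adjusted p = 0.787 with an estimated correlation). Oxidative phosphorylation genes were lower (-0.27, camera adjusted p = 0.000762; adjusted p = 0.534 with an estimated correlation). Myeloid and dendritic cell markers were lower (-0.43, camera adjusted p = 0.0372) and mitochondrially encoded genes higher (0.68, 0.000606), again each with adjusted p = 0.787 with an estimated correlation. Of their members 0 were called over all genes in edgeR or limma-voom. Lower when adjusted over the list alone were 6 cell cycle, 3 oxidative phosphorylation and 1 heat shock genes, with 0 in the other lists. DESeq2 called 6, 3 and 1 lower, and 1 myeloid gene. At an unadjusted p under 0.05 these lists had 12, 7, 7 and 3 lower members, with 1 higher in the heat shock and 1 in the mitochondrial list. The mitochondrial call was lost without WT replicate 2 of 8 weeks (adjusted p = 0.334), and the cell cycle and heat shock calls without WT replicate 3 of 8 weeks (0.217 and 0.251) and among the libraries of 8 threads (0.601 and 0.408). The myeloid call was lost without WT replicate 2 of 20 weeks (0.337) or WT replicate 1 (0.0878) or 2 (0.0965) of 8 weeks.

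In knockout-labelled cells the same group of genes fell between 8 and 20 weeks. Nr4a1 fell from 171 ± 73 to 24.6 ± 5.95 CPM (n = 3 each; log2 fold change -2.80, SE 0.38, adjusted p = 0.0157), Fos from 817 ± 275 to 207 ± 23.2 CPM (-1.98, SE 0.25, adjusted p = 0.0144) and Tnfaip3 from 200 ± 30.6 to 44.2 ± 9.3 CPM (-2.18, SE 0.25, adjusted p = 0.0144). Tph1, which encodes the first enzyme of serotonin synthesis, fell from 20.7 ± 10.9 to 2.23 ± 0.458 CPM (-3.21, SE 0.41, adjusted p = 0.0144). The other called genes were Nr4a2 (-3.87), Rasd1 (-2.56), Dusp1 (-1.90), Cd69 (-1.80, lost in 12 of 22 alternatives) and Cdkn1a (-1.80). Of 25 immediate early genes 6 fell over all genes and 14 adjusted over the list alone (median -0.88, camera adjusted p = 8.78e-34; adjusted p = 0.00714 with an estimated correlation), with a call in all 17 alternatives. In the interaction this list did not pass the test (median 0.21, camera adjusted p = 0.11). Of 9 genes called, 0 were higher in edgeR or limma-voom, while the DESeq2 Wald test called 32 higher and 118 lower, and 1202 genes had an unadjusted p under 0.05 in edgeR. The 9 became 0 without knockout-labelled replicate 1 or 2 of 20 weeks or replicate 2 of 8 weeks, and 1 without replicate 3 of 20 weeks. The count was 6 without replicate 1 of 8 weeks, 26 without replicate 3 of 8 weeks and 59 without both libraries that stood apart. With the thread number as a covariate edgeR called 0, limma-voom 4 and DESeq2 58. There 756 had an unadjusted p under 0.05, among them all 9 genes in the same direction. This fit uses the libraries that chose the 9 genes and is no separate support.

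**Figure D3:**
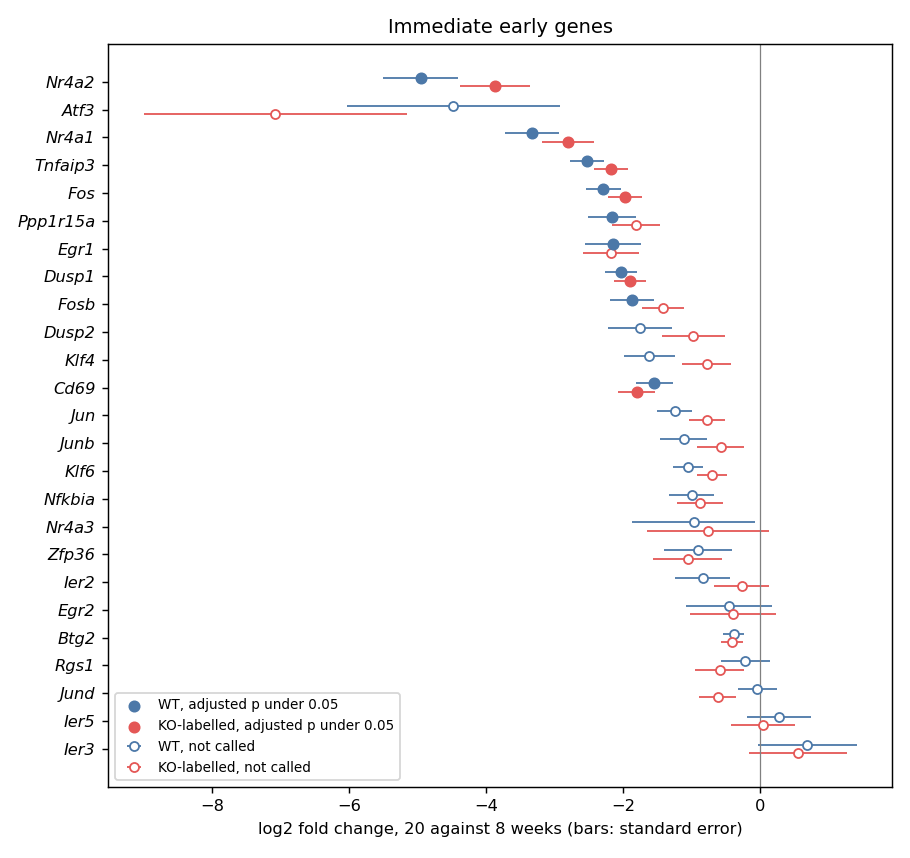
Log2 fold change of 20 against 8 weeks, with its standard error (bars), for the 25 tested immediate early genes in WT (blue) and knockout-labelled cells (red), with called genes filled. In both genotypes 2 members lay above 0, and the largest called decreases were those of Nr4a2 (-4.96 in WT and -3.87 in knockout-labelled cells).

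The time contrasts of WT and knockout-labelled cells share no library. In both, 8 genes fell: Tnfaip3, Fos, Nr4a1, Cdkn1a, Dusp1, Nr4a2, Cd69 and Rasd1, against 0.028 expected for independent contrasts. Both donors' cells came from mixed chimeras, and equal replicate numbers were read as pairs at 8 weeks. The contrasts may therefore share mice and any batch that went with time, so the overlap is not one of independent results. Across the 14431 genes the Pearson correlation of both sets of log2 fold changes was 0.4. In knockout-labelled cells interferon-stimulated genes (median -1.07, camera adjusted p = 8.69e-20) and cell cycle genes (-0.31, 1.53e-07) were lower as lists. So were oxidative phosphorylation (-0.23, 0.000141) and heat shock and unfolded protein response genes (-0.34, 5.32e-05). Each of these 4 had an adjusted p = 0.234 with an estimated correlation. Among their members 0 were called over all genes in edgeR or limma-voom, while DESeq2 called 10, 6, 1 and 1 lower. At an unadjusted p under 0.05, 19, 12, 7 and 5 were lower. Lower when adjusted over the list alone were 15 interferon-stimulated genes and 9 cell cycle genes, among them the replication clamp gene Pcna (-0.94, SE 0.18). B cell markers had a median of -2.24 (camera adjusted p = 2.34e-08; adjusted p = 0.234 with an estimated correlation), with 0 members called over all genes in edgeR or limma-voom and 4 lower in DESeq2. Of the list, 10 were lower adjusted over its members alone, and also 10 at an unadjusted p under 0.05. Neuropeptide and lipid mediator receptors were higher as a list (0.39, camera adjusted p = 0.0261; adjusted p = 0.234 with an estimated correlation). Mitochondrially encoded genes were also higher (0.43, camera adjusted p = 0.0478; adjusted p = 0.741 with an estimated correlation), and 0 members of either list were called in edgeR, limma-voom or DESeq2 or adjusted over the list alone (1 higher in each at an unadjusted p under 0.05). The receptor call was lost without knockout-labelled replicate 2 of 20 weeks (adjusted p = 0.0671) or replicate 3 of 8 weeks (0.279). The mitochondrial call was lost without knockout-labelled replicate 3 of 20 weeks (0.368), WT replicate 1 of 8 weeks (0.0601) or knockout-labelled replicate 2 (0.174) or 3 (0.291) of 8 weeks, and with the thread number as a covariate (0.839). Among single ILC2 genes, Areg, which encodes amphiregulin, had a log2 fold change of -1.83 in WT cells (SE 0.40, adjusted p = 0.0758) and -1.31 in knockout-labelled cells (SE 0.39, adjusted p = 0.385). Il13 had a log2 fold change of -0.42 in WT cells (SE 0.32, adjusted p = 0.619) and -1.53 in knockout-labelled cells (SE 0.33, adjusted p = 0.215), with an interaction of -1.11 (SE 0.46, unadjusted p = 0.0315, adjusted p = 1).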

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

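The test of the Y-linked genes on X-linked partners was set before its result was seen, while the tests of a single mislabelled library, of donor sex as a cause of other genes and of the WT libraries of 8 weeks were chosen after the results were seen.

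Each result given here drew attention because the genotype difference changed between 8 and 20 weeks in a test of that change itself. The change in log2 units was 6.92 for Capn11, 5.12 for Hectd4, 3.47 for Adamts13, 2.87 for Fmo1 and 2.63 for Cdk5rap1. It was -11.16 for Nefh, a fitted value against a group at 0 and therefore no bound, -6.19 for Eif2s3y, -5.94 for Ddx3y, -4.59 for Uty, -2.74 for Mid1 and -2.03 for Pes1. Among gene lists the median change was -2.66 for B cell markers, -0.35 for type 2 cytokines and effectors and 0.68 for mast cell, basophil and eosinophil markers. Libraries were reassigned freely within each time in 100 splits. Of these, 2 gave as many interaction calls as the 14 of the real split, itself included. The splits did not keep the replicate numbers together, so chance is not excluded for the count if the numbers mark pairs. The highest other split gave 32. It exchanges the genotype labels at 1 time and so turns the interaction into the average.

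The Y-linked genes Ddx3y, Eif2s3y and Uty were high in all 3 WT libraries of 20 weeks and near 0 elsewhere. A single mislabelled library is argued against, since 0 libraries of other groups exceeded 10 CPM of Ddx3y. Male donor marrow for the WT cells of 20 weeks, with female donors for the rest, is a candidate explanation. It was tested on 5 genes that escape X inactivation, which a male cell carries once. They had a median log2 fold change of -0.58 in the WT libraries of 20 weeks, from -0.65 for Kdm6a to 0.25 for Ddx3x. The Y gene Kdm5d was at 51.5 ± 2.47 CPM in these libraries. It stayed at 20.1 ± 2.41 CPM in WT cells of 8 weeks. In knockout-labelled cells it was at 24.7 ± 8.62 CPM at 8 weeks and 26.6 ± 2.11 CPM at 20 weeks. Female donors for those groups would not account for these reads, whose source was not tested. Donor sex as the cause of the other genes called at 20 weeks is argued against for 3 of the 4 off the Y chromosome. These moved the same way at 8 weeks, where Ddx3y, Eif2s3y and Uty were low in both genotypes. For Capn11, which moved the other way, donor sex as the cause stays open. Donor sex was not stated in the labels, and in WT cells any effect of it was measured together with that of time.

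The WT libraries of 8 weeks differed from all other libraries in a set of 19 genes called both between genotypes at 8 weeks and between times in WT cells, among them Capn11, Fmo1, Adamts13, Cdk5rap1, Pes1, Nefh and Mid1. A single library is argued against: with each WT library of 8 weeks held out and the genes chosen anew without it, it lay beyond the other 9 libraries in at least 93.8% of them (11 of 11, 15 of 16 and 22 of 22). Time acting alike in both genotypes, as the whole cause of the set, is argued against by holding out each knockout-labelled library of 8 weeks. With the genes chosen anew, the median change in knockout-labelled cells in the direction of WT was at most 0.05 log2 units. Its upper quartile was at most 0.75, and the median change in WT was at least 2.38. The interaction called 10 of the 19 genes, but it uses the libraries that chose the set and is no separate support. Inherited DNA segments that differ in the WT donors of 8 weeks may account for part of the set, since 7 pairs of the genes lay within 2 Mb (permutation p = 0.0001, the smallest 10000 draws can give; 95th percentile of random draws 2), of which 6 came from 1 cluster on chromosome 11 that holds Pes1, Gal3st1 and Nefh. In that cluster a gene model without an ordinary symbol overlaps Pes1, and Gal3st1 lies next to it. The other pair was Mid1 and a neighbouring gene model on the X chromosome. The draws were of single genes and do not allow for overlapping or adjacent genes that change together. Nothing in the labels describes such donors, and a difference between genotypes that appears only at 8 weeks stays open for the genes outside the cluster.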

How the results depend on the processing

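Leaving out both 8-week libraries that stood apart, the fits by thread number and the 10 Mb window with the replicate block were chosen after the data were seen; the other settings were fixed beforehand. Of 90 called values of named genes 0 changed sign, 14 stayed past the threshold in every setting and 19 were lost in more than 10. Of 126 values not called, 43 were called in at least 1 setting and 7 changed sign in at least 1: Ptprc, Il1rl1, Il5, Il13 and Icos in the average, Fos at 8 weeks and Jag1 in the interaction. Counts under DESeq2 size factors, no filter, the stricter filter, limma-voom and length-scaled counts stayed within 1.5 times those reported. The order here is genotype at 20 weeks, at 8 weeks and averaged, interaction, time in WT and time in knockout-labelled cells. The DESeq2 Wald test called 32, 75, 76, 35, 498 and 150 genes, all those called by edgeR among them; the cause was not tested. The fit of only the groups compared called 17 and 8 between genotypes at 20 and 8 weeks, the reverse of the order in the shared fit (8 and 29). It called 37 and 0 between times in WT and knockout-labelled cells (for the 0, limma-voom 0, DESeq2 244 and unadjusted 1252 in the same libraries). Each spread then rested on fewer samples and was not shared with the other groups, and the cause of the changed order was not tested. Without both libraries that stood apart the counts were 20, 38, 44, 27, 156 and 59, of which 8, 23, 29, 14, 70 and 9 genes were shared with those reported. With the thread number as a covariate they were 3, 29, 28, 10, 57 and 0 (for the 0, limma-voom 4, DESeq2 58, unadjusted 756). Among the libraries of 8 threads genotype at 8 weeks and time in WT gave 0 and 0 (limma-voom 0 and 0, DESeq2 50 and 218, unadjusted 467 and 1147). Leaving out single libraries gave 3 to 15, 15 to 36, 23 to 36, 10 to 16, 29 to 302 and 0 to 26; the cause of the rise without WT replicate 3 of 8 weeks was not tested. At an unadjusted p under 0.05 the genotype calls of both times shared 47 genes, against 3 adjusted.

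With the replicate number as a block, 4, 15, 19, 9, 49 and 5 genes were called, 1 was shared by both times, and the odds ratio of the hand-written lists near both loci was 9.25 (exact p = 0.109). In the 10 Mb window around both loci it was 16.8 with the block (exact p = 0.000199). Every library correlated best with that of its own number at the same time. For the genotype contrasts and the interaction the block was the replicate number within a time. For the time contrasts it was the number across both times, and nothing links equal numbers of different times. The 49 and 5 genes and the list calls of the time contrasts therefore do not test pairs within a time. Of 26 list calls 2 held in every setting, 24 were lost with an estimated correlation and 20 with fry, 0 with the block, 1 with threads as a covariate, 4 of 11 among the libraries of 8 threads and 7 without both libraries that stood apart.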

Other observations

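Of the tests below, that of Rag1 loss as the whole cause of the calls near Rag1 and Thy1 was chosen after the result was seen, as was the look at genes known to vary between C57BL/6 substrains.

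Genes for the repair of double-strand breaks, the lesion that the Rag1 enzyme makes, were not called as a list between genotypes. Averaged over times, 21 of 24 members had a positive log2 fold change, with a median of 0.12 (camera adjusted p = 0.108), 0 were called over all genes in edgeR, limma-voom or DESeq2 or adjusted over the list alone, and 2 were higher at an unadjusted p under 0.05. Prkdc, the catalytic subunit of the kinase that joins broken ends, was at 0.31 (SE 0.14, adjusted p = 1). The p53 targets had a median of 0.03 (camera adjusted p = 0.766). Signalling and receptor lists were as close: immediate early genes -0.08 (0.55), costimulation and checkpoint receptors -0.09 (0.55), NF-kB and IL-33 signalling 0.01 (0.91), targets and brakes of IL-2, IL-7 and STAT5 -0.05 (0.781), and neuropeptide and lipid mediator receptors -0.08 (0.566), each a median log2 fold change with its camera adjusted p. Cell cycle genes had a median of 0.06 (0.55), interferon-stimulated genes 0.11 (0.55), MHC class I and antigen processing -0.02 (0.826) and naive-like and progenitor genes 0.06 (0.91).

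Metabolic lists gave medians of 0.03 for glycolysis (camera adjusted p = 0.737), 0.00 for sterol synthesis (0.8), 0.09 for fatty acid uptake and use (0.55), -0.01 for oxidative phosphorylation (0.646), 0.09 for heat shock and unfolded protein response (0.55) and -0.22 for mitochondrially encoded genes (0.627). Markers of other cell types in the same average had medians of 0.25 for B cells (0.55), -0.07 for myeloid and dendritic cells (0.826), -0.06 for NK cells and ILC1 (0.91), 0.02 for ILC3 and type 17 cells (0.55), -0.04 for mast cells, basophils and eosinophils (0.737), -0.15 for stromal and endothelial cells (0.91) and -0.12 for erythroid cells and platelets (0.737). Keratinocyte markers had 2 tested members with a median of 0.10, and of 4 tested sex-linked genes 3 were lower, too few in each for a list test. Counted over all genes in edgeR or limma-voom, 0 members of the lists in these paragraphs were called apart from the sex-linked genes, while DESeq2 also called 1 checkpoint receptor and 1 sterol synthesis gene lower. Adjusted over the list alone, 1 checkpoint receptor gene and 1 sterol synthesis gene were lower and 1 stromal gene was higher. At an unadjusted p under 0.05 no list held more than 2 members, apart from the sex-linked genes.

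Because Rag1 is needed to assemble antigen receptors, reads on receptor segments were summed. T cell receptor V segments, 132 genes, were at 112 ± 27.7 and 98.6 ± 18.7 CPM in WT and knockout-labelled cells of 8 weeks and at 104 ± 10.7 and 110 ± 10.7 CPM at 20 weeks. Rearranged receptors of mature B and T cells in the WT libraries cannot be told from other sources by this sum (1-sided exact permutation p = 0.395, 6 against 6 libraries, smallest possible 0.0025), because transcripts of segments that were never joined count as well. T cell receptor constant segments, 7 genes, were higher in WT. They were at 1350 ± 180 against 1040 ± 209 CPM at 8 weeks and 1100 ± 50.3 against 961 ± 112 CPM at 20 weeks. The exact permutation p was 0.0075, and its Benjamini-Hochberg adjusted p was 0.03 over the 4 classes of segments. This permutation did not keep the replicate numbers together, so its p may not hold if they mark pairs. Immunoglobulin V segments followed the B cell markers, at 5.65 ± 2.17 and 72.1 ± 80.8 CPM at 8 weeks and 53.6 ± 17.3 and 4.41 ± 1.87 CPM at 20 weeks for WT and knockout-labelled cells (exact p = 0.598), and immunoglobulin constant segments likewise changed direction. These were at 132 ± 64.4 and 209 ± 165 CPM at 8 weeks, higher in the knockout-labelled library of each replicate number, and at 199 ± 53.4 and 88.2 ± 17.2 CPM at 20 weeks, higher in each WT library (exact p = 0.415 over both times).

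The genes called in the average clustered near Thy1, while the excess near Rag1 did not pass the test with the replicate block (exact p = 0.11). Loss of Rag1 acting on genes anywhere in the genome, as the whole cause, is argued against by the lower bound of the odds ratio for both windows, 10.1 (4.03 with the block). Reads lost to sequence differences of the CD90.1 segment, as the whole cause, are argued against. Of the genes near Thy1 with an unadjusted p under 0.05, 48.3% were lower in knockout-labelled cells (14 lower and 15 higher). Such a loss would make nearly all of them higher, or nearly all lower if the genotype labels were exchanged. Donor-strain DNA linked to the targeted or congenic locus is consistent with the odds ratio of 25.2 and may underlie the calls of Thy1, Tmprss13 and Nxpe4, which held with the block. For Itgae, Me3 and Asb18, which lie on other chromosomes, the effect of Rag1 on the cells stays open and untested. Me3, like Ets1, is also among the 19 genes that set the WT libraries of 8 weeks apart. For Jag1, on the chromosome of Rag1 but outside the window, linked DNA and an effect of Rag1 were not told apart.

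For the genotype average, chance is argued against under splits drawn freely within each time. The real split called 32 genes and the highest of 99 others 14, the split that exchanges genotype at 1 time. These splits did not keep the replicate numbers together, so they do not exclude chance if the numbers mark pairs. For the contrasts of 3 against 3 libraries the 10 splits are too few for a share under 0.05. There the real split was the 1 with the highest count, 8 against 0 in the next for genotype at 20 weeks, 29 against 3 at 8 weeks, 74 against 0 for time in WT and 9 against 0 for time in knockout-labelled cells.

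Among genes known to vary between C57BL/6 substrains, chosen after their values were seen, Wdfy1 was at 100 ± 18.7 CPM in WT cells of 8 weeks and at 42.8 to 47.4 CPM in the other groups (log2 fold change -1.12 at 20 against 8 weeks, adjusted p = 0.0895). Entpd4 was at 2.82 ± 0.582 CPM in the same group and 5.81 to 7.62 CPM elsewhere (1.44, adjusted p = 0.0443, a call lost in 16 of 23 alternatives). Nnt was not called (-0.18, adjusted p = 0.745). Between genotypes at 8 weeks none of these genes was called. There the log2 fold changes were -1.23 for Wdfy1 (adjusted p = 0.144), 1.05 for Entpd4 (adjusted p = 0.461) and -0.31 for Nnt. The gene for beta-actin, Actb, also chosen afterwards, was at 242000 CPM in knockout-labelled replicate 3 of 8 weeks, at 29400 and 42700 CPM in the other 2 libraries of its group, and at group means of 42400 to 67200 CPM elsewhere.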
